A study of Arabidopsis thaliana with 18 samples.

How the data were processed

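The samples were dry Arabidopsis seeds of the abci20 mutant and of Col-0, collected at harvest, with total, polysomal and monosomal RNA from 3 biological replicates of each genotype. Per the labels' protocols, the plants grew in a randomized complete block layout in which a replicate was a bulk of plants, RNA was extracted with TriPure and cleaned on RNeasy columns, and cRNA was made with a 3-prime one-cycle kit. The labels give biotin as the label. How well signals from a 3-prime kit reflect the levels of chloroplast- and mitochondrion-encoded transcripts was not examined. Per the submitters' processing notes, the authors summarized the arrays with RMA, whose version is not given in the sources used here, and the deposited values are log2 signals. Nothing in the sources used here says whether all arrays were processed together. The deposited values range from 0.301 to 12.71 for 27827 probe sets, 1 per locus, in 18 arrays. No scan-level data were used, so probe-level quality was not examined, and the number of arrays limits the precision.

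Samples were grouped by the genotype and RNA fraction in their labels, which gave 6 groups of 3 arrays. The same replicate number was taken as the same block and, within a genotype, the same seed bulk, from the stated layout. As a check, residual correlations between arrays of the same number were compared in 7 pairs of groups: 7 of 21 pairs exceeded 0.1, and they ran from -0.166 to 0.245. The fit without a replicate block was the main one because no model is stated, and the block, which was an alternative, gave 971 genes against 932 in total RNA.

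Probe sets were named from a reference table of locus tags and symbols, which matched 27241 of them and left 586 under their locus. There were 0 control probe sets to remove, and no intensity filter was applied. All 18 arrays were fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with 1 coefficient per group and 12 residual degrees of freedom (4 where only the 6 compared arrays were fitted). Each probe set thus had 1 spread for all 3 fractions, which is a limit where the fractions differ in spread. The moderated tests were two-sided, and Benjamini-Hochberg adjustment ran over all probe sets of a comparison at 0.05. The 9 comparisons were abci20 against Col-0 in each fraction, polysomal against total and polysomal against monosomal RNA in each genotype, and the genotype difference of each of these fraction contrasts. Robust estimation used statmod 1.5.0, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

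Gene lists, the rule for named genes, the comparisons and the alternatives, except those named as added, were fixed before the data were examined. The 21 lists covered the ABCI family, seed storage proteins, oil body proteins, late embryogenesis abundant proteins, seed maturation and dormancy regulators, abscisic acid, gibberellin and cytokinin genes, photosynthesis, cytosolic ribosomal proteins, translation factors, heat shock proteins, endoplasmic reticulum chaperones, storage lipid synthesis, storage lipid breakdown, antioxidant enzymes, seed coat markers, endosperm markers, jasmonate and defence, and the genes encoded in chloroplasts and in mitochondria. Of 323 fixed members, 9 were left out because the reference table gives their locus another symbol, and 1 was not measured. Lists were tested against all other genes with camera at a preset correlation of 0.01 and at an estimated correlation, adjusted over the 21 lists of a comparison. Counts of members past the threshold were adjusted over all genes, and also over the list alone.

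A probe set that matches several genes was to be neither named nor used in a list. Which probe sets this covers was recognised only after the lists had first been tested: 182 had values identical to another's on every array, among them 37 mitochondrion-encoded, 12 chloroplast-encoded and 1 other list member. They were then left out of the lists, which took the mitochondrion-encoded list from 92 to 55 members and the chloroplast-encoded list from 15 to 3.

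Named genes were ABCI20, then the 12 higher and 12 lower genes with the largest fitted change past the threshold in each genotype comparison, the 8 higher and 8 lower in each fraction comparison in Col-0 with their abci20 values, the 10 with the smallest p in each interaction, and the 4 members of each list with the smallest p. The text gives a part of them, and genes outside the rule are named as chosen after their values were seen.

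The alternatives were a replicate block (adjusted p = 0.0675 for seed coat markers in polysomal RNA), only the compared groups in the fit, quantile normalization, each array centred on its median, only probe sets whose highest group mean exceeded the median of that value, a variance trend with robust estimation, array weights, and leaving out each compared array in turn. Alternatives chosen after seeing the data were the 12 arrays of the gradient fractions alone, leaving out abci20 total replicate 1 where it lies outside the comparison, scaling of the list tests, keeping the identical probe sets, and all alternatives for the genes shared by the 3 fractions. The fit was tested on simulated data with the same design, with 50 genes changed at each of 4 sizes. At 2 log2, 80% of changed genes passed in the total RNA comparison and 58% in the genotype difference of polysomal against total RNA. At 1 log2 these were 32% and 8%. All 4 sizes were simulated together, and 8 of 149 and 3 of 93 genes that passed were unchanged. The simulated arrays shared 1 spread per gene, so unequal spread between arrays or fractions was not covered.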

Results

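Transcript levels were measured on arrays in dry Arabidopsis seeds of the abci20 mutant and of Col-0, its background. ABCI20 belongs to the ABC transporter superfamily, and the series addresses its role in seed maturation. Each genotype was represented by total RNA, polysomal RNA (messages carrying several ribosomes) and monosomal RNA (messages carrying a single ribosome), with 3 arrays for each of the 6 groups and 18 arrays in all. A replicate was a bulk of plants, so the 3 genotype comparisons share no arrays but, if like numbers stand for the same bulk in every fraction, share their seed bulks. The values were RMA log2 signals from 0.301 to 12.71 for 27827 probe sets, and the number of arrays limits their precision. A fitted difference between groups of 3 had a median standard error of 0.291 log2 across probe sets. Array abci20 total replicate 1 stood apart: across genes it correlated with abci20 total replicates 2 and 3 at r = 0.893 and 0.915, against 0.959 between those. Genes are not independent replicates in these correlations.

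ABCI20 (AT5G02270) was low in every mutant array. In total RNA its level was 4.42, 4.02 and 3.80 log2 in the Col-0 replicates and 1.88, 1.1 and 2.33 in the abci20 replicates. In polysomal RNA the corresponding levels were 4.23, 4.49 and 4.39 against 2.37, 1.61 and 2.16, and in monosomal RNA 3.84, 5.09 and 4.37 against 2.41, 2.06 and 1.64. ABCI20 fell by 2.31 log2 (SE 0.341, 4.96-fold, adjusted p = 0.00151) in total RNA, by 2.32 (5.0-fold, adjusted p = 0.00406) in polysomal RNA and by 2.40 (5.27-fold, adjusted p = 0.00195) in monosomal RNA. The mutant signal lay between percentiles 2.59 and 38.7 of all probe sets of an array, close to background, which limits how large these folds can be. The fitted changes of its relatives ABCI19 and ABCI21 in total RNA were -0.54 (adjusted p = 0.377) and -0.36 (adjusted p = 0.476).

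**Figure D1:**
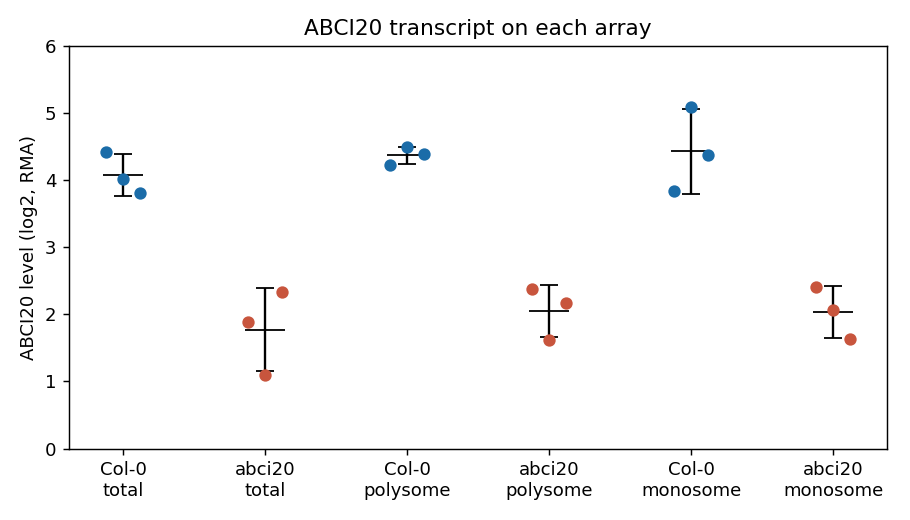
ABCI20 signal (RMA log2, vertical axis) in each of the 18 arrays by genotype and RNA fraction, with points for arrays and bars for the mean ± SD (n = 3). The highest abci20 array is at 2.41 and the lowest Col-0 array at 3.80.

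The comparison of abci20 with Col-0 in total RNA asked how the seed's whole message pool differed at maturity. The gene with the smallest adjusted p among those named was AT1G71250, a GDSL lipase family gene, which rose by 3.02 log2 (SE 0.217, 8.14-fold, n = 3 per genotype, adjusted p = 2.51e-06). NRT2.6, a nitrate transporter family gene, rose by 2.83 (SE 0.329, adjusted p = 0.000362), CCL, whose message is unstable and under clock control, by 2.51 (SE 0.341, adjusted p = 0.000892), and HSP21, a chloroplast small heat shock protein, by 2.27 (SE 0.312, adjusted p = 0.00095). The growth-regulating factor gene GRF5 (AT3G13960) rose by 2.15 (SE 0.419) and PSBO2, of the oxygen-evolving complex, by 2.04 (SE 0.393). AT2G43590 fell by 3.01 (SE 0.398, 8.05-fold, adjusted p = 0.000733), AT5G66430 by 2.99 (SE 0.303) and the organ growth gene ARL by 2.82 (SE 0.32, adjusted p = 0.000339). The strigolactone synthesis gene CCD7 fell by 2.57 (SE 0.288) and EBF2, an F-box gene of ethylene signalling, by 2.52 (SE 0.278).

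With 1 spread per probe set for all arrays, 932 of the 27827 probe sets passed the threshold in total RNA under limma. They were 310 higher and 622 lower in the mutant. Of these, 246 were higher and 353 lower by at least 2-fold. At an unadjusted p under 0.05 there were 4857 probe sets (17.5%). The count was 0 when only the 6 compared arrays entered the fit (2765 at an unadjusted p under 0.05), 1701 among the brighter probe sets and 1520 with a variance trend. It was 2640 (1295 higher, 1345 lower) without abci20 total replicate 1, 504 without abci20 total replicate 2, and 457, 619 and 355 without Col-0 total replicates 1, 2 and 3. Without abci20 total replicate 1, 850 of the 932 remained past the threshold in the same direction. A regrouping of the same 6 arrays that mixed the genotypes gave 929 genes. The count of 932 alone therefore does not set a genotype effect apart from other structure of the samples. Centring each array on its median moved the median change of all genes by -0.142 log2 and the split to 169 higher and 923 lower (15.5% higher, against 33.3%). Of 25 named genes past the threshold, 20 stayed past it whichever array was left out, while AT1G69900, AT1G22067, AT1G03890, AT1G26400 and AT1G21528 did not. For AT1G69900 (2.16, adjusted p = 0.0493) the adjusted p was 0.189 without abci20 total replicate 2, and for AT1G21528 (2.28, adjusted p = 0.0171) it was 0.0898 without Col-0 total replicate 3.

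Among the gene lists, heat shock proteins were higher in mutant total RNA: 5 of 17 rose and 0 fell (6 and 0 adjusted over the list alone), with a median of 0.38 log2. Their adjusted p was 1.08e-05, and adjusted p = 0.122 with an estimated correlation. HSP17.6II rose by 1.52, HSP18.2 by 1.3 and AT5G51440 by 1.01. Cytosolic ribosomal protein genes had a median of 0.35 (adjusted p = 0.000918, and adjusted p = 0.309 with an estimated correlation), although 0 of 26 passed singly, also adjusted over the list alone. In the list of abscisic acid metabolism and signalling 5 of 26 fell (median -0.17, adjusted p = 0.00782, and adjusted p = 0.101 with an estimated correlation; 2 higher and 8 lower adjusted over the list alone). These included the phosphatases HAI1 (-1.41), HAI2 (-1.03), ABI1 (-0.96) and PP2CA (-0.82), which restrain abscisic acid signalling, and the synthesis gene ABA1 (-0.73).

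Late embryogenesis abundant proteins, seed storage proteins and storage lipid breakdown were lower in mutant total RNA at the preset correlation, but not with an estimated correlation. Oil body proteins and storage lipid synthesis did not pass, and the median of storage lipid synthesis was higher in the mutant. Late embryogenesis abundant proteins had a median of -0.23 with 1 of 21 members positive (adjusted p = 0.00235, and adjusted p = 0.309 with an estimated correlation), and 0 passed singly, also adjusted over the list alone. Seed storage proteins had a median of -0.25 (adjusted p = 0.0197, and adjusted p = 0.349 with an estimated correlation), with 1 of 10 past the threshold, the cruciferin-like AT1G03890 (-2.34, SE 0.563, adjusted p = 0.0298). AT1G03890 missed it after quantile normalization (adjusted p = 0.0516) and without any of 4 arrays (adjusted p = 0.0974 without abci20 total replicate 2, 0.0956, 0.0585 and 0.0855 without Col-0 total replicates 1, 2 and 3). CRU2, a cruciferin, had a fitted change of -0.49 (adjusted p = 0.194). Storage lipid breakdown had a median of -0.32 (adjusted p = 0.00265, and adjusted p = 0.295 with an estimated correlation), and 2 of 18 fell (0 higher and 3 lower adjusted over the list alone), the acyl-CoA oxidase genes ACX1 (-0.79) and ACX3 (-0.80). Photosynthesis genes had a median of 0.37 (adjusted p = 0.0197, and adjusted p = 0.309 with an estimated correlation), with PSBO2 higher and LHCB4.1 lower (-1.04) among 33 (2 and 1 adjusted over the list alone). The family list of ABCI19, ABCI20 and ABCI21 had a median of -0.54 (adjusted p = 0.00782, and adjusted p = 0.122 with an estimated correlation), with only ABCI20 past the threshold. As ABCI20 is the disrupted gene, the call of this list in any fraction restates its loss and says nothing of ABCI19 and ABCI21.

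Quantile normalization ended the calls of storage proteins (adjusted p = 0.179), late embryogenesis abundant proteins (0.14), photosynthesis (0.0584) and storage lipid breakdown (0.0978) in total RNA. Without abci20 total replicate 1 the adjusted p was 0.0773 for the ABCI family, 0.0969 for storage proteins, 0.0531 for late embryogenesis abundant proteins, 0.0969 for photosynthesis and 0.124 for storage lipid breakdown. Without Col-0 total replicate 1 it was 0.0781 for the ABCI family and 0.0949 for storage proteins, without abci20 total replicate 2 it was 0.0515 for storage proteins, and without Col-0 total replicate 2 it was 0.08 for photosynthesis. Among the brighter probe sets it was 0.0679 for the ABCI family, 0.0967 for storage proteins, 0.0823 for the abscisic acid list and 0.0872 for photosynthesis, and with array weights 0.129 for storage proteins and 0.0895 for storage lipid breakdown.

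The remaining lists did not pass in total RNA. Their medians were -0.28 for oil body proteins (adjusted p = 0.0711), -0.12 for seed maturation regulators (0.688), 0.18 for gibberellin metabolism and signalling (0.124), -0.02 for cytokinin (0.972), 0.03 for translation factors (0.956) and 0.12 for endoplasmic reticulum chaperones (0.248). They were 0.40 for storage lipid synthesis (adjusted p = 0.0644), -0.11 for antioxidant enzymes (0.34), 0.13 for seed coat markers (0.0752), 0.09 for endosperm markers (0.956), 0.11 for jasmonate and defence (0.0752), 0.63 for 3 chloroplast-encoded genes (0.668) and -0.05 for 55 mitochondrion-encoded genes (0.825). The mean of the mitochondrion-encoded genes, 0.083, had the opposite sign to their median and test. Single members of these lists passed, among them the oleate desaturase FAD2 (1.23), GA20OX3 (1.69) and GA2OX2 (1.19) of gibberellin metabolism, the catalase CAT1 (-1.16), the mannanase MAN5 (-1.41) and AOS (1.68), of jasmonate synthesis.

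The polysomal comparison asked which messages differed between genotypes among those carrying several ribosomes in the dry seed. HSP21 rose by 2.89 log2 (7.39-fold, n = 3 per genotype, adjusted p = 0.000257) and NRT2.6 by 2.69 (adjusted p = 0.000821). The tocopherol methyltransferase gene G-TMT rose by 2.21 (SE 0.303, adjusted p = 0.00243), the CONSTANS-like gene COL5 by 2.04 (SE 0.266, adjusted p = 0.00178), the sterol synthesis gene DWF1 by 1.99 (SE 0.28), the flavonoid hydroxylase gene TT7 by 1.96 (SE 0.225, adjusted p = 0.000497) and the hexose transporter gene MSS1 by 1.87 (SE 0.267). ARL fell by 2.97 (7.86-fold, adjusted p = 0.000257), the transcription factor gene NAC019 by 2.87 (SE 0.285, adjusted p = 0.000257), EBF2 by 2.29 (adjusted p = 0.000821) and the peptide transporter gene PTR5 by 1.76 (SE 0.264, adjusted p = 0.00415).

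In polysomal RNA 123 probe sets passed under limma, 65 higher and 58 lower, with 60 and 54 of them changed at least 2-fold. At an unadjusted p under 0.05 there were 2211 (7.95%). The count was 423 with only the 6 compared arrays in the fit, 67 with each array centred on its median, 264 among the brighter probe sets, 286 with a variance trend, 2657 with array weights, 222 with the 12 gradient arrays alone and 215 without abci20 total replicate 1, which lies outside the comparison. It was 32, 27 and 70 without abci20 polysome replicates 1, 2 and 3, and 32, 50 and 42 without Col-0 polysome replicates 1, 2 and 3. Centring gave 27 higher and 40 lower (40.3% higher, against 52.8%). Of 24 named genes past the threshold, 18 stayed past it whichever array was left out. The chalcone synthase gene TT4 (2.06, SE 0.404, adjusted p = 0.0327) did not: its adjusted p was 0.159 after quantile normalization, 0.0682 after centring, 0.184, 0.136 and 0.0783 without abci20 polysome replicates 1, 2 and 3, and 0.194, 0.126 and 0.0726 without Col-0 polysome replicates 1, 2 and 3. CCL (2.2, adjusted p = 0.00585) reached 0.0621 without abci20 polysome replicate 2 and 0.059 without Col-0 polysome replicate 1, and the clock gene PRR5 (1.92, adjusted p = 0.00456) reached 0.0529 without abci20 polysome replicate 2.

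Heat shock proteins were again higher in the mutant's polysomes: 4 of 17 rose and 0 fell (9 and 0 adjusted over the list alone), with a median of 0.57 (adjusted p = 3.89e-13, and adjusted p = 0.0152 with an estimated correlation). Besides HSP21 these were HSP17.6II (1.64), AT1G52560 (1.13) and AT5G51440 (0.97). Endoplasmic reticulum chaperones had a median of 0.45 (adjusted p = 0.000218, and adjusted p = 0.0238 with an estimated correlation), with 0 of 12 past the threshold singly and 1 higher adjusted over the list alone. The fitted changes were 1.38 for SHD (adjusted p = 0.123) and 0.91 for BIP1. Cytosolic ribosomal protein genes had a median of 0.43 with 25 of 26 positive (adjusted p = 1.57e-11, and adjusted p = 0.0517 with an estimated correlation), 0 of them past the threshold singly and 2 higher adjusted over the list alone.

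In the abscisic acid list ABI1 fell by 1.65 and NCED9, a synthesis gene, rose by 1.09 in polysomal RNA. Its median was -0.33 (adjusted p = 0.00357, and adjusted p = 0.0238 with an estimated correlation), with 1 higher and 3 lower adjusted over the list alone. The 55 mitochondrion-encoded transcripts had a median of -0.35 with 4 positive (adjusted p = 9.53e-06, and adjusted p = 0.35 with an estimated correlation), and 0 passed singly, also adjusted over the list alone. Their median level in an array, averaged over arrays, was 7.44 ± 0.156 log2 (SD, n = 3) in Col-0 and 7.0 ± 0.0454 in abci20. Late embryogenesis abundant proteins had a median of -0.18 (adjusted p = 0.00108, and adjusted p = 0.285 with an estimated correlation; 0.107 without Col-0 polysome replicate 2), with 0 of 21 past the threshold. The ABCI family had a median of -0.66 (adjusted p = 2.69e-05, and adjusted p = 0.0152 with an estimated correlation), with ABCI20 past the threshold and 2 of 3 lower adjusted over the list alone. It holds the disrupted gene, and ABCI19 (-0.49, adjusted p = 0.812) and ABCI21 (-0.66, adjusted p = 0.354) did not pass over all genes.

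Jasmonate and defence genes had a median of 0.06 in polysomal RNA (adjusted p = 0.0158, and adjusted p = 0.217 with an estimated correlation; 0.0618 with array weights), with AOS (1.36) alone past the threshold, also adjusted over the list alone. Without abci20 polysome replicate 3 that median was -0.01 (adjusted p = 0.118). Seed coat markers had a median of 0.01, which was -0.02 after centring, with adjusted p = 0.0377, and adjusted p = 0.099 with an estimated correlation. Their adjusted p was 0.0675 with the replicate block, 0.147 with only the compared groups in the fit, 0.0581 with the 12 gradient arrays, 0.16 with array weights (median -0.06), 0.103 without abci20 polysome replicate 3 and 0.107 without Col-0 polysome replicate 2. TT7, TT4 and F3H (1.05), 3 of 18 seed coat markers, rose in the mutant's polysomes, also adjusted over the list alone, and all belong to flavonoid synthesis. The other lists had adjusted p from 0.0884 for translation factors to 0.984. In seed maturation regulators, antioxidant enzymes, endosperm markers and chloroplast-encoded genes, the median, mean and test differed in sign.

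The monosomal comparison asked the same of messages with a single ribosome. CCL rose by 3.04 log2 (8.21-fold, n = 3 per genotype, adjusted p = 0.000305), AT5G11420 by 2.59, AT1G71250 by 2.58 (5.98-fold, adjusted p = 2.39e-05), TT7 by 2.48 (adjusted p = 2.39e-05), HSP21 by 2.46 (adjusted p = 0.00107), COL5 by 2.45 (adjusted p = 0.000224) and the ubiquitin ligase gene XBAT31 by 2.43 (SE 0.349, adjusted p = 0.00203). NAC019 fell by 3.16 (SE 0.285, adjusted p = 2.39e-05), AT3G19615 by 2.67 (SE 0.24, adjusted p = 2.39e-05), ARL by 2.39 (adjusted p = 0.00147) and EBF2 by 2.15 (adjusted p = 0.00125).

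In monosomal RNA 510 probe sets passed under limma, 303 higher and 207 lower, with 251 and 160 of them changed at least 2-fold. At an unadjusted p under 0.05 there were 4139 (14.9%). The count was 25 with only the 6 compared arrays in the fit, 316 with each array centred on its median, 1087 among the brighter probe sets, 970 with a variance trend, 977 with the 12 gradient arrays alone and 955 without abci20 total replicate 1. It was 160 and 100 without abci20 monosome replicates 1 and 2, and 142 and 211 without Col-0 monosome replicates 1 and 3. Of 24 named genes past the threshold, 16 stayed past it whichever array was left out. Among the others, LCR30 (-3.11, SE 0.564, adjusted p = 0.0101) reached 0.065 without abci20 monosome replicate 2 and 0.0577 without Col-0 monosome replicate 1, and the kinase gene MAPKKK19 (-2.40, adjusted p = 0.0115) reached 0.0549 and 0.0742 without abci20 monosome replicates 1 and 2 and 0.0547 and 0.0561 without Col-0 monosome replicates 1 and 3.

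Heat shock proteins had a median of 0.49 in monosomal RNA, with 5 of 17 higher and 0 lower (8 and 0 adjusted over the list alone; adjusted p = 6.44e-10, and adjusted p = 0.0512 with an estimated correlation). Cytosolic ribosomal protein genes had a median of 0.49 with 25 of 26 positive (adjusted p = 2.65e-09, and adjusted p = 0.115 with an estimated correlation), 0 past the threshold singly and 9 higher adjusted over the list alone. Mitochondrion-encoded transcripts had a median of -0.34 (adjusted p = 4.47e-05, and adjusted p = 0.47 with an estimated correlation), and ATMG01280 (-0.88) and ATMG00490 (-0.88) fell, 2 also adjusted over the list alone. Storage lipid synthesis had a median of 0.35 (adjusted p = 0.00977, and adjusted p = 0.0788 with an estimated correlation; 0.0508 without Col-0 monosome replicate 2 and 0.0997 among the brighter probe sets), and FAD2 rose by 1.19, with 2 higher adjusted over the list alone. Jasmonate and defence genes had a median of 0.16 (adjusted p = 0.0271, and adjusted p = 0.242 with an estimated correlation), and WRKY33 (2.06) and AOS (1.40) rose, 2 also adjusted over the list alone. That list's adjusted p was 0.0987 without abci20 monosome replicate 3, 0.0776 and 0.0644 without Col-0 monosome replicates 1 and 3, 0.0748 among the brighter probe sets and 0.0583 with the 12 gradient arrays. The ABCI family had a median of -0.66 (adjusted p = 0.00476, and adjusted p = 0.0788 with an estimated correlation), with ABCI20, the disrupted gene, past the threshold but not ABCI19 (-0.66, adjusted p = 0.306) or ABCI21 (-0.30, adjusted p = 0.627). The other lists had adjusted p from 0.0525 for translation factors to 0.976. Seed maturation regulators did not pass as a list (adjusted p = 0.243), but ABI4 (1.80, adjusted p = 0.0089) and EEL (0.77, adjusted p = 0.0357), transcription factors of abscisic acid responses, rose. Seed coat markers (adjusted p = 0.486) had a median of -0.06 and a mean of 0.155.

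**Figure D2:**
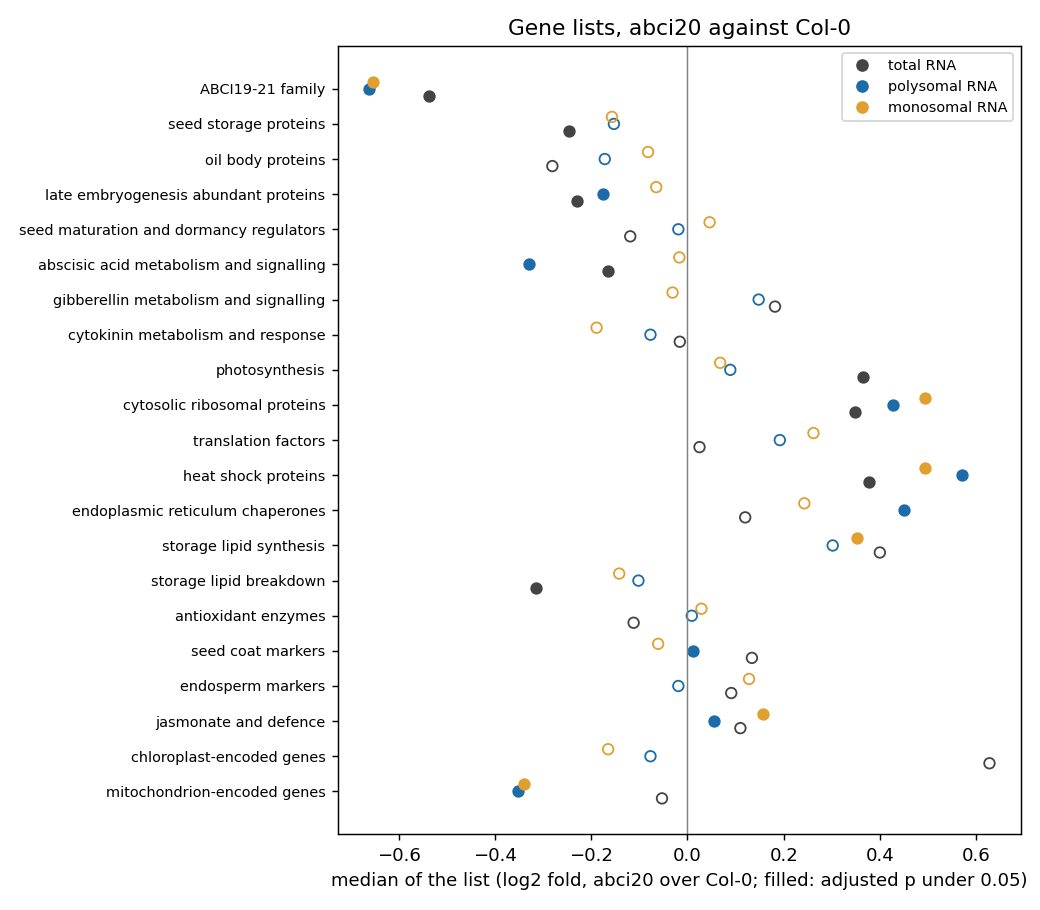
Median fitted change of each gene list, abci20 minus Col-0 (log2, horizontal axis), in total, polysomal and monosomal RNA (n = 3 arrays per genotype), with filled symbols for lists past the camera threshold at the preset correlation. Heat shock proteins lie at 0.38, 0.57 and 0.49 and cytosolic ribosomal proteins at 0.35, 0.43 and 0.49.

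A set of 81 genes passed the threshold in the same direction in all 3 fractions, 41 higher and 40 lower. Total and polysomal RNA shared 47 higher and 49 lower genes. Total and monosomal RNA shared 108 and 123, and polysomal and monosomal RNA shared 49 and 41. Across all genes, which are not independent replicates, the changes correlated at r = 0.431 for total and polysomal, 0.353 for total and monosomal and 0.52 for polysomal and monosomal RNA. Where the fractions come from the same seed bulks, chance differences between bulks add to the overlaps and correlations, and no value without a genotype effect was computed for the pairwise overlaps or the correlations. The shared count was 0 with only the compared arrays in each fit, 49 after centring, 193 among the brighter probe sets, 194 with a variance trend and 191 with array weights. It was 137 without abci20 total replicate 1, 26 and 23 without abci20 polysome replicates 1 and 2, 28, 37 and 34 without Col-0 polysome replicates 1, 2 and 3, and 47 and 46 without abci20 monosome replicates 1 and 2.

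Some of the shared genes given here were chosen after their values were seen and were not tested as groups. In total, polysomal and monosomal RNA in turn, the changes were 1.89, 2.04 and 2.45 for COL5, 1.82, 1.96 and 2.48 for TT7, 1.44, 2.21 and 1.82 for G-TMT, and 1.18, 1.92 and 2.18 for PRR5. NRT2.6 was higher by 2.83, 2.69 and 1.90, the nitrite reductase gene NIR1 by 1.01, 1.24 and 1.18, and the siroheme synthesis gene UPM1 by 1.22, 1.16 and 1.56. The small heat shock protein genes HSP17.6II (1.52, 1.64 and 1.72) and ATHSP22.0 (1.61, 1.53 and 1.64) were higher, as was the RNA-binding protein gene GRP7 (1.82, 1.41 and 1.56). Among the lower genes were NAC019 (-1.84, -2.87 and -3.16), CCD7 (-2.57, -1.67 and -1.86), the salicylic acid synthesis gene EDS16 (-2.04, -1.63 and -1.33), ABI1 (-0.96, -1.65 and -1.31) and the ethylene signalling gene EIN2 (-1.06, -1.26 and -1.28).

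**Figure D3:**
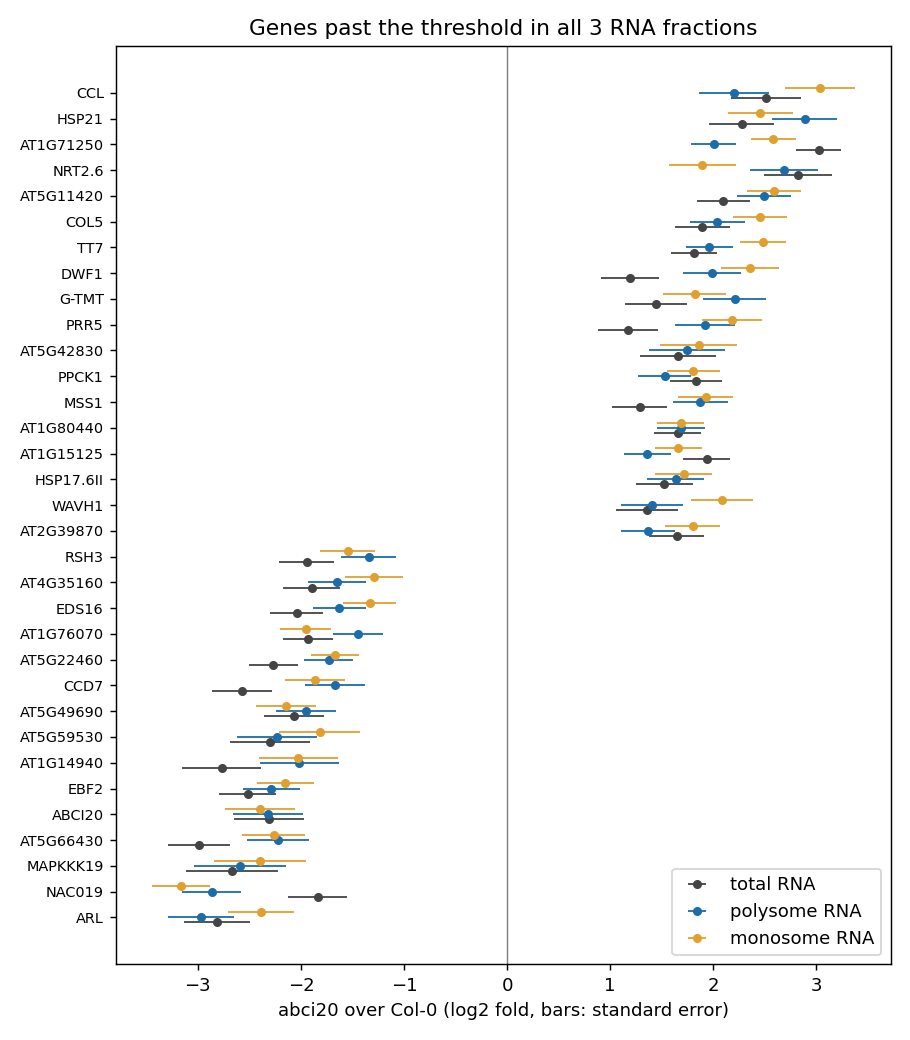
Fitted change, abci20 minus Col-0 (log2, horizontal axis), of the 33 genes past the threshold in all 3 fractions with the largest mean change, with 1 symbol per fraction, bars for the standard error and n = 3 arrays per genotype. NAC019 lies at -1.84, -2.87 and -3.16 and HSP21 at 2.27, 2.89 and 2.46.

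Polysomal was compared with total RNA within each genotype to show which messages were over- or under-represented on polysomes in dry seeds. In Col-0 the coatomer subunit gene AT1G62020 was higher on polysomes by 2.18 log2 (SE 0.322, 4.54-fold, n = 3 per fraction, adjusted p = 0.0024) and AT4G09587 by 2.51 (SE 0.402, adjusted p = 0.00358). In abci20 the same genes were higher by 1.58 (adjusted p = 0.00393) and 2.24 (adjusted p = 0.00194). The extensin gene EXT10 was lower on polysomes by -4.63 in Col-0 (SE 0.601, 24.7-fold, adjusted p = 0.00123) and by -5.91 in abci20 (60-fold, adjusted p = 6.55e-05), and its Col-0 polysomal level of 1.51, against 6.13 in total RNA, was near background. AT4G09649 changed by -4.31 and -4.69. AT5G19257 and AT1G34910 also fell in both genotypes, but their polysomal levels, 1.58 and 2.71 in Col-0 and 1.43 and 1.76 in abci20, were near background and limit their folds. Of the 16 genes named in Col-0, 12 also passed in abci20. AT1G15160 did not: it was 1.95 in Col-0 (adjusted p = 0.0178) and -0.62 in abci20 (adjusted p = 0.339), and its genotype difference of -2.57 had an adjusted p of 0.999.

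In Col-0 1985 probe sets passed in polysomal against total RNA under limma, 1131 higher and 854 lower, 581 and 735 of them by at least 2-fold. In abci20 6149 passed, 3304 higher and 2845 lower, 1366 and 2288 of them by at least 2-fold. At an unadjusted p under 0.05 there were 6786 (24.4%) and 10044 (36.1%). The Col-0 count was 517 after quantile normalization (236 higher, 45.6% against 57%), 3202 after centring (2529 higher, 79%), 4899 with array weights and 3649 without abci20 total replicate 1. It was 1145 and 619 without Col-0 total replicates 1 and 2, and 516, 703 and 426 without Col-0 polysome replicates 1, 2 and 3. The abci20 count was 1590 with only the compared arrays in the fit, 2575 after quantile normalization and 11135 with array weights, and centring gave 6820 higher and 1767 lower (79.4% higher, against 53.7%). It was 9163 without abci20 total replicate 1, 3395 and 3898 without abci20 total replicates 2 and 3, and 3076, 3948 and 3621 without abci20 polysome replicates 1, 2 and 3. Centring moved the median change of all genes by 0.213 log2 in Col-0 and 0.324 in abci20. Of the named genes, 10 of 16 in Col-0 and 10 of 12 in abci20 stayed past the threshold whichever array was left out. The splicing factor subunit gene SAP130a (2.0, SE 0.511, adjusted p = 0.0276) reached 0.0723 after quantile normalization and 0.0979 and 0.0811 without Col-0 total replicates 1 and 2, and 0.0817, 0.0584 and 0.11 without Col-0 polysome replicates 1, 2 and 3. AT1G15160 reached 0.0767 without Col-0 total replicate 2 and 0.0901 without Col-0 polysome replicate 3.

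Mitochondrion-encoded transcripts were lower in polysomal than in total RNA in both genotypes at the preset correlation, but not with an estimated correlation. Whether those in the polysomal fraction were bound to ribosomes was not tested. The cRNA was made with a 3-prime kit, and how well its signals reflect organelle transcript levels was not examined. In Col-0 their median change was -0.96 (adjusted p = 3.13e-09, and adjusted p = 0.24 with an estimated correlation), with 1 of 55 higher and 22 lower (5 and 30 adjusted over the list alone). In abci20 it was -1.06 (adjusted p = 8.47e-11, and adjusted p = 0.343 with an estimated correlation), with 3 higher and 29 lower (3 and 30 adjusted over the list alone). ATMG00820 fell by 4.04, ATMG00770 by 2.77 and ATMG00360 by 1.54 in Col-0. The median level of the list in an array of total RNA, averaged over arrays, was 8.53 ± 0.313 log2 (SD, n = 3) in Col-0 and 8.31 ± 0.862 in abci20, where abci20 total replicate 1 had 7.31 and the other arrays 8.78 and 8.83. Chloroplast-encoded genes had a median of -0.87 in Col-0, with 2 of 3 lower, also adjusted over the list alone (adjusted p = 0.00612, and adjusted p = 0.24 with an estimated correlation), and ATCG00250 fell by 3.1. Their median level in an array of total RNA, averaged over arrays, was 7.98 ± 1.29 in Col-0 and 8.85 ± 1.51 in abci20. Col-0 total replicate 3 had 6.50 against 8.87 and 8.58 in the other Col-0 arrays, and abci20 total replicate 1 had 7.13 against 9.95 and 9.48.

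**Figure D4:**
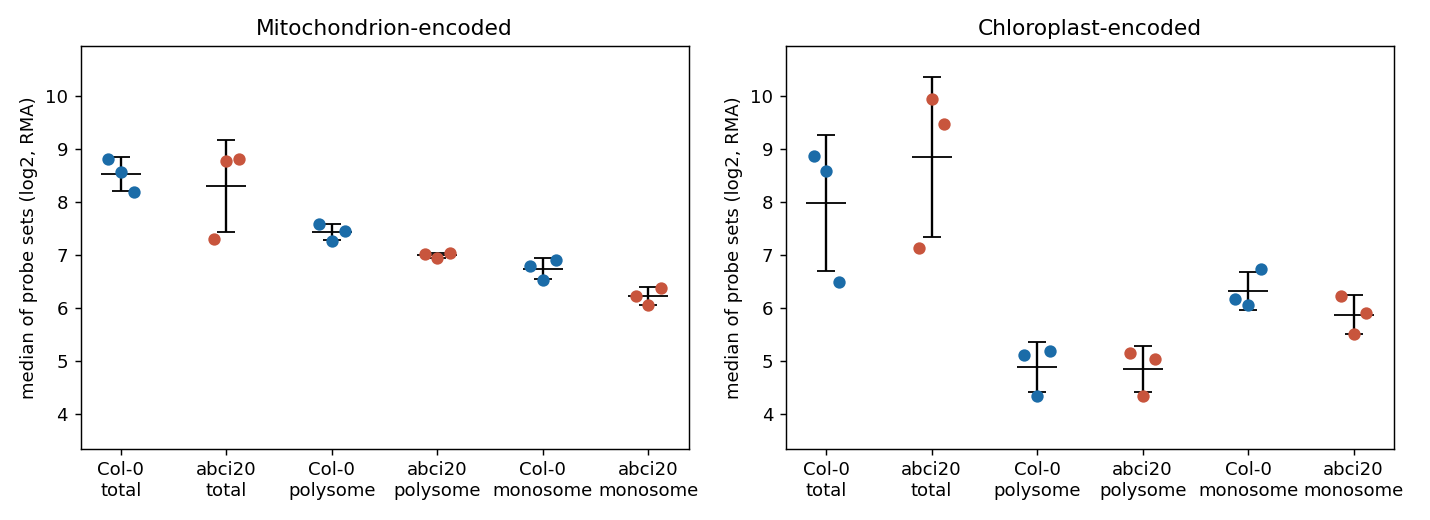
Median signal (RMA log2, vertical axis) of the 55 mitochondrion-encoded and 3 chloroplast-encoded genes in each array by genotype and RNA fraction, with points for arrays and bars for the mean ± SD of these medians (n = 3). The averages of the mitochondrion-encoded medians are 8.53, 7.44 and 6.74 in Col-0 total, polysomal and monosomal RNA and 8.31, 7.0 and 6.22 in abci20.

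Late embryogenesis abundant proteins were lower on polysomes than in total RNA, with a median of -0.40 and 6 of 21 lower in Col-0 (0 higher and 10 lower adjusted over the list alone; adjusted p = 1.82e-06, and adjusted p = 0.24 with an estimated correlation). In abci20 the median was -0.39 and 7 were lower (9 adjusted over the list alone; adjusted p = 0.00115, and adjusted p = 0.462 with an estimated correlation; 0.0797 after centring). ECP63 fell by 0.91 and AT2G42560 by 0.81 in Col-0. Seed storage proteins had a median of -0.35 in Col-0 (adjusted p = 0.00494, and adjusted p = 0.299 with an estimated correlation), with SESA2, an albumin gene, lower by -0.94 and 4 of 10 lower adjusted over the list alone. Heat shock proteins had a median of -0.20 in Col-0, which was 0.01 after centring, with 3 of 17 lower, also adjusted over the list alone (adjusted p = 0.0197, and adjusted p = 0.327 with an estimated correlation; 0.086 after centring). That list's adjusted p was 0.0934 and 0.0546 without Col-0 polysome replicates 1 and 3.

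Storage lipid breakdown genes were higher on polysomes, with a median of 0.29 in Col-0 (adjusted p = 0.00379, and adjusted p = 0.24 with an estimated correlation) and 0.53 in abci20 (adjusted p = 0.000101, and adjusted p = 0.237 with an estimated correlation). In Col-0 1 of 18 rose (2 adjusted over the list alone), and in abci20 9 rose (11 adjusted over the list alone). Translation factors had medians of 0.43 in Col-0 (adjusted p = 0.00379, and adjusted p = 0.22 with an estimated correlation) and 0.53 in abci20 (adjusted p = 0.00115, and adjusted p = 0.138 with an estimated correlation), and eIFiso4G1 (0.96) and the elongation factor gene LOS1 (0.94) rose in Col-0. Of the 14 translation factors 2 rose in Col-0 (4 adjusted over the list alone) and 7 in abci20 (7 adjusted over the list alone). The abscisic acid list had medians of 0.39 in Col-0 (adjusted p = 0.00379, and adjusted p = 0.0625 with an estimated correlation) and 0.31 in abci20 (adjusted p = 0.00719, and adjusted p = 0.102 with an estimated correlation), and the synthesis genes ABA3 (1.16), NCED6 (1.02) and NCED5 (1.05) rose in Col-0. Of its 26 members 3 rose in Col-0 (4 adjusted over the list alone), and in abci20 10 rose and 1 fell (12 and 1 adjusted over the list alone). Cytosolic ribosomal proteins had medians of 0.21 in Col-0 (adjusted p = 0.0194, and adjusted p = 0.548 with an estimated correlation) and 0.41 in abci20 (adjusted p = 0.00555, and adjusted p = 0.462 with an estimated correlation), and 2 and 5 of 26 rose (4 and 5 adjusted over the list alone).

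Quantile normalization ended the polysomal over total calls of storage proteins (adjusted p = 0.18), ribosomal proteins (0.299) and translation factors (0.0817) in Col-0, and of the abscisic acid list (0.0949), ribosomal proteins (0.174) and translation factors (0.118) in abci20. For ribosomal proteins the adjusted p was 0.0771 without Col-0 total replicate 1, 0.128 without Col-0 polysome replicate 2 and, in abci20, 0.058 without abci20 total replicate 3. Among the brighter probe sets the adjusted p in Col-0 was 0.161 for the abscisic acid list, 0.548 for ribosomal proteins, 0.108 for translation factors and 0.0712 for storage lipid breakdown, and in abci20 0.393, 0.401 and 0.0981 for the abscisic acid list, ribosomal proteins and translation factors. In endoplasmic reticulum chaperones in Col-0, and in seed maturation regulators and heat shock proteins in abci20, the median, mean and test differed in sign.

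Polysomal was also compared with monosomal RNA, which contrasts messages with several ribosomes and messages with 1. The gene BIG, which encodes a very large protein of auxin transport, was higher in polysomal RNA by 2.86 log2 in Col-0 (SE 0.184, 7.23-fold, n = 3 per fraction, adjusted p = 4.62e-07) and by 3.16 in abci20 (8.96-fold, adjusted p = 8.85e-08). AT5G23110 was higher by 2.92 (SE 0.2, adjusted p = 6.01e-07) and 2.88, AT1G62020 by 2.86 and 2.27, and AT4G17140 by 2.78 and 2.67. Among genes lower in polysomal RNA, the metallothionein gene MT1A changed by -2.30 in Col-0 (SE 0.358, 4.92-fold, adjusted p = 0.000625) and -2.10 in abci20, the coactivator gene KELP by -2.27 (SE 0.292, adjusted p = 0.000145) and -2.42, and the peptide precursor gene PROPEP5 by -2.26 (SE 0.24, adjusted p = 3.56e-05) and -2.15. Of 16 genes named in Col-0, 15 also passed in abci20. The other, AT1G09900, was 2.92 in Col-0 (SE 0.647, adjusted p = 0.00727) and 1.27 in abci20 (adjusted p = 0.23).

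In Col-0 3467 probe sets passed in polysomal against monosomal RNA under limma, 2283 higher and 1184 lower, 1441 and 574 of them by at least 2-fold. In abci20 2994 passed, 2034 higher and 960 lower, 1248 and 513 of them by at least 2-fold. At an unadjusted p under 0.05 there were 8185 (29.4%) and 7078 (25.4%). The Col-0 count was 2070 after quantile normalization, 5496 with array weights and 5384 with the 12 gradient arrays alone, and centring gave 2325 higher and 636 lower (78.5% higher, against 65.8%). It was 1963, 1965 and 1730 without Col-0 polysome replicates 1, 2 and 3 and 2179 without Col-0 monosome replicate 1. The abci20 count was 7029 with array weights, quantile normalization gave 1160 higher and 912 lower (56% higher, against 67.9%), and it was 1475 and 1730 without abci20 polysome replicates 1 and 3. Quantile normalization moved the median change of all genes by 0.117 log2 in Col-0 and 0.101 in abci20, from -0.128 and -0.111. All 16 genes named in Col-0 stayed past the threshold whichever array was left out, as did 13 of 15 in abci20. AT3G50550 in abci20 (-1.56) reached 0.0528 after centring and missed the threshold without each of the 6 arrays: 0.122, 0.061 and 0.0897 without abci20 polysome replicates 1, 2 and 3, and 0.0627, 0.115 and 0.0612 without abci20 monosome replicates 1, 2 and 3. AT5G22545 in abci20 (-1.99) reached 0.0655 and 0.0742 without abci20 polysome replicates 1 and 3 and 0.0765 without abci20 monosome replicate 3.

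Mitochondrion-encoded transcripts were higher in polysomal than in monosomal RNA, with a median of 0.68 and 16 of 55 higher in Col-0 (21 adjusted over the list alone; adjusted p = 5.79e-08, and adjusted p = 0.377 with an estimated correlation). In abci20 the median was 0.63 and 17 were higher (22 adjusted over the list alone; adjusted p = 1.82e-09, and adjusted p = 0.345 with an estimated correlation). ATMG00960 (2.39) and ATMG00570 (2.08) rose in Col-0. Late embryogenesis abundant proteins were lower in polysomal RNA, with 8 of 21 past the threshold in each genotype, a median of -0.51 in Col-0 (13 lower adjusted over the list alone; adjusted p = 4.36e-06, and adjusted p = 0.219 with an estimated correlation) and -0.53 in abci20 (15 lower adjusted over the list alone; adjusted p = 5.86e-09, and adjusted p = 0.114 with an estimated correlation). Translation factors had medians of 0.68 in Col-0 (adjusted p = 0.000296, and adjusted p = 0.0769 with an estimated correlation) and 0.63 in abci20 (adjusted p = 0.000684, and adjusted p = 0.114 with an estimated correlation). In Col-0 EIF4G rose by 1.75 and EIF4E fell by 0.82, and 6 of 14 rose and 1 fell in each genotype (10 and 2 in Col-0, 8 and 2 in abci20 adjusted over the list alone). Storage lipid breakdown had medians of 0.39 in Col-0 (adjusted p = 0.00134, and adjusted p = 0.299 with an estimated correlation) and 0.51 in abci20 (adjusted p = 8.54e-05, and adjusted p = 0.187 with an estimated correlation), and the storage lipase gene SDP1 rose by 0.70 in Col-0. Of 18 members 4 rose in Col-0 (7 adjusted over the list alone) and 5 in abci20 (8 adjusted over the list alone).

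Heat shock proteins had medians of -0.47 in Col-0, with 6 of 17 lower (2 higher and 7 lower adjusted over the list alone; adjusted p = 0.0237, and adjusted p = 0.425 with an estimated correlation), and -0.59 in abci20, with 1 higher and 7 lower (2 and 9 adjusted over the list alone; adjusted p = 0.00867, and adjusted p = 0.357 with an estimated correlation). Seed storage proteins had medians of -0.43 in Col-0 (adjusted p = 0.0254, and adjusted p = 0.425 with an estimated correlation) and -0.41 in abci20 (adjusted p = 0.0228, and adjusted p = 0.517 with an estimated correlation), and the albumin genes SESA2, SESA3 and SESA5 fell in Col-0, with 3 of 10 lower in each genotype, also adjusted over the list alone. The abscisic acid list had medians of 0.38 in Col-0 (adjusted p = 0.0127, and adjusted p = 0.0769 with an estimated correlation) and 0.32 in abci20 (adjusted p = 0.0154, and adjusted p = 0.114 with an estimated correlation). In Col-0 5 of its 26 members rose and 2 fell (8 and 2 adjusted over the list alone), and in abci20 2 rose and 1 fell (4 and 1 adjusted over the list alone). Oil body proteins had a median of -0.44 in abci20 (adjusted p = 0.0274, and adjusted p = 0.406 with an estimated correlation), and the oleosin gene OLEO3, 1 of 6 also adjusted over the list alone, fell by 0.60.

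Quantile normalization ended the polysomal over monosomal calls of storage proteins (adjusted p = 0.301) and the abscisic acid list (0.0979) in Col-0, and of storage proteins (0.507), oil body proteins (0.322) and the abscisic acid list (0.139) in abci20, and centring ended that of storage proteins in Col-0 (0.0532). For heat shock proteins in Col-0 the adjusted p was 0.0648 without Col-0 polysome replicate 1 and 0.108 without Col-0 monosome replicate 2, and for storage proteins 0.0514 without Col-0 polysome replicate 3 and 0.0567 without Col-0 monosome replicate 2. In abci20, storage and oil body proteins had 0.124 and 0.133 without abci20 polysome replicate 2 and 0.0708 and 0.0656 without abci20 monosome replicate 3. With only the compared groups in the fit the adjusted p was 0.0586 for storage proteins and 0.0783 for heat shock proteins in Col-0 and 0.0705 and 0.0874 for storage and oil body proteins in abci20. With array weights it was 0.0584 and 0.0573 for storage and oil body proteins in abci20, with the 12 gradient arrays 0.0517 for heat shock proteins in Col-0, and among the brighter probe sets 0.312 for the abscisic acid list in Col-0 and 0.214 and 0.0626 for that list and translation factors in abci20. The median, mean and test differed in sign in Col-0 for the ABCI family, endoplasmic reticulum chaperones, antioxidant enzymes and endosperm markers, and in abci20 for antioxidant enzymes.

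**Figure D5:**
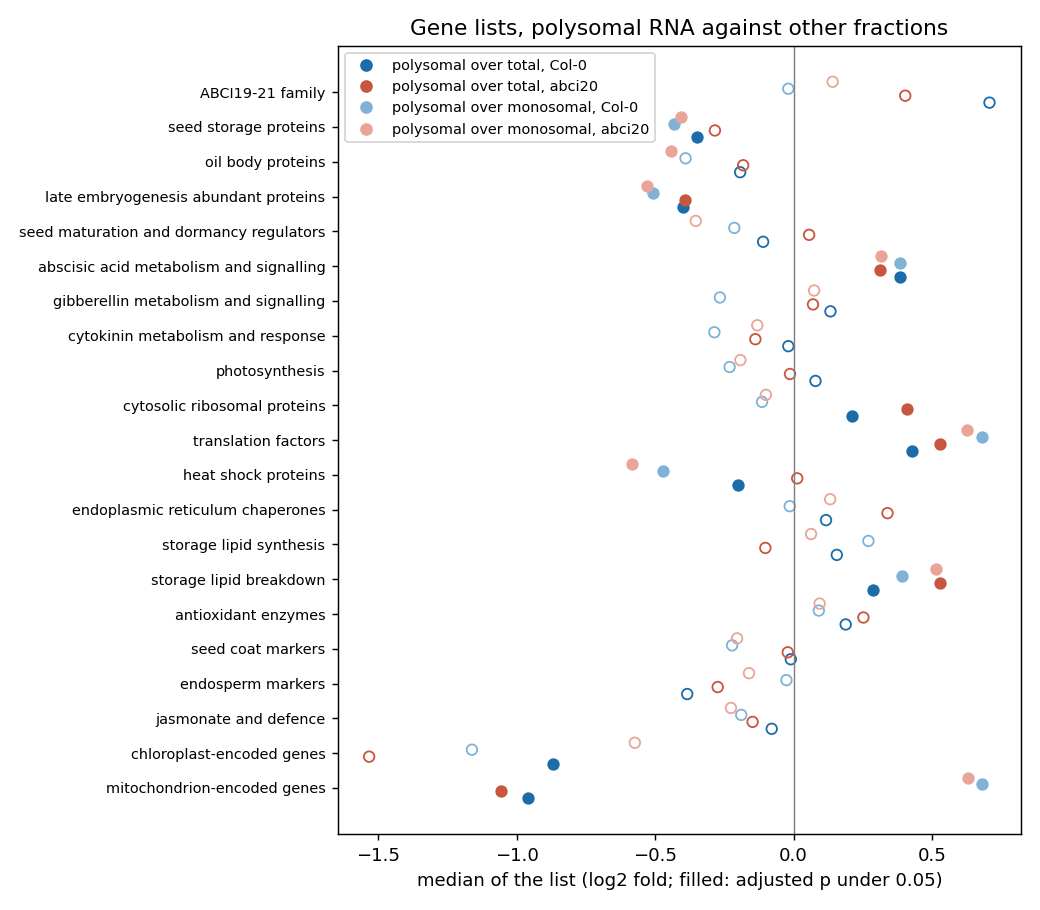
Median fitted change of each gene list between RNA fractions (log2, horizontal axis), polysomal minus total and polysomal minus monosomal, in Col-0 and abci20 (n = 3 arrays per fraction), with filled symbols for lists past the camera threshold at the preset correlation. Mitochondrion-encoded genes lie at -0.96 and -1.06 against total RNA and at 0.68 and 0.63 against monosomal RNA.

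Whether the mutant distributed messages among the fractions differently from Col-0 was tested as an interaction. For polysomal over total RNA the smallest p belonged to AT3G44840 (-1.50 log2, SE 0.333), and MED22B, a Mediator subunit gene, had a genotype difference of 1.98 (SE 0.454), each with an adjusted p of 0.999. For polysomal over monosomal RNA AT5G39180 had a genotype difference of 1.92 (SE 0.335, adjusted p = 0.66) and ACHT3, a thioredoxin gene, of 1.71 (adjusted p = 0.908). Under limma 0 probe sets passed in either, with 1263 (4.54%) and 744 (2.67%) at an unadjusted p under 0.05 and a median standard error of 0.412 log2. Genes called in 1 genotype or fraction alone are therefore not shown to differ between them. For polysomal over total RNA 28 passed without abci20 total replicate 1 (3 higher, 25 lower), among them AT1G52660 (-1.66, adjusted p = 0.0358), and for polysomal over monosomal RNA 2 passed with array weights. Centring moved the median interaction of all genes for polysomal over total RNA by 0.111 log2.

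As lists, 2 groups differed between genotypes in polysomal over total RNA. Storage lipid breakdown genes had a median genotype difference of 0.27 with 16 of 18 positive (adjusted p = 0.0379, and adjusted p = 0.897 with an estimated correlation). Mitochondrion-encoded transcripts had a median of -0.27 with 14 of 55 positive (adjusted p = 0.0143, and adjusted p = 0.897 with an estimated correlation). In each list 0 members passed singly under limma, also adjusted over the list alone. Without abci20 total replicate 1 the lipid breakdown list had a median of 0.11 (adjusted p = 0.671), and it also missed the threshold after quantile normalization (0.584), with only the compared groups in the fit (0.0825), among the brighter probe sets (0.111), with array weights (0.428), without Col-0 total replicates 1, 2 and 3 (0.0838, 0.0634 and 0.179), without abci20 polysome replicates 1 and 3 (0.162 and 0.0821) and without Col-0 polysome replicates 1 and 2 (0.0842 and 0.092). The mitochondrion-encoded list missed it without abci20 total replicates 2 and 3 (0.549 and 0.433), Col-0 total replicate 3 (0.296), abci20 polysome replicate 2 (0.193) and Col-0 polysome replicate 3 (0.0564). For polysomal over monosomal RNA 0 of 21 lists passed.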

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

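All tests of the array that stands apart and of the mitochondrion-encoded transcripts were chosen only after the result was seen. The splits of the samples and the test of loci near ABCI20 were written beforehand.

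For 2 lists the polysomal over total ratio differed between abci20 and Col-0 by a test of that difference at the preset correlation, but for neither with an estimated correlation (adjusted p = 0.897 for each), and 0 members passed singly under limma. Storage lipid breakdown had a median difference of 0.271 log2 (adjusted p = 0.0379, and adjusted p = 0.897 with an estimated correlation), with polysomal minus total medians of 0.822, 0.418 and 0.34 in the abci20 bulks and 0.376, 0.387 and 0.366 in the Col-0 bulks, which overlap. Without abci20 total replicate 1 the median difference was 0.11 (adjusted p = 0.671).

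Mitochondrion-encoded transcripts had a median difference of -0.27 log2 (adjusted p = 0.0143, and adjusted p = 0.897 with an estimated correlation), the more negative ratio being that of abci20. Under quantile normalization and centring the median nearest 0 was -0.16, so neither scaling brought it to the bound of -0.1. That bound was set after the result was seen, and no spread was computed for the value, so scaling of the arrays is not excluded as a source. Chance spread between seed bulks stays open and could account for the difference. The bulk medians were -0.58, -1.312 and -1.282 in abci20 and -1.121, -0.665 and -0.568 in Col-0. The lowest Col-0 bulk minus the highest abci20 bulk was -0.541, so the genotypes overlapped. This overlap rests on abci20 bulk 1 (-0.58), which holds abci20 total replicate 1, the array that stands apart. The other abci20 bulks, at -1.312 and -1.282, lay below every Col-0 bulk, so the overlap does not decide the question. These bulk values take like-numbered arrays as the same bulk. The genotype itself is a biological explanation that also stays open.

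Array abci20 total replicate 1 correlated less with its own group (r = 0.893 and 0.915 across genes) than the other members did with each other (0.959), and received an array weight of 0.204. A purely polysomal sample under a wrong label is argued against, since its highest correlation with an abci20 polysomal array was 0.953 and polysomal arrays correlated at 0.970 to 0.987 with each other. It was nevertheless closer to polysomal arrays than to its own group, so a partly mixed sample may be an explanation and was not tested. Col-0 RNA is argued against by its ABCI20 level of 1.88, against 3.80 to 4.42 in Col-0 total arrays, and noise of dim probe sets alone by a mean correlation of 0.868 over the brighter probe sets, against 0.950 to 0.961 for other total arrays of a genotype. The other arrays of that number did not stand apart from their groups (r = 0.987 and 0.986 for polysomal, 0.969 and 0.967 for monosomal RNA), which goes against a difference of the whole seed bulk if like numbers are the same bulk, and no biological explanation was tested further.

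The many genes that differed between genotypes might have lain in DNA linked to the ABCI20 locus, had the lines differed there. Of the 40 nearest measured loci, 20 on each side and not counting ABCI20, 0 differed in at least 1 fraction under limma at an adjusted p of 0.05, where 1.77 would follow from the 4.41% of all genes that did. These loci showed no excess of differing genes, but 0 is close to 1.77, and 40 loci are too few to place the 1228 genes that differed. Linked DNA further from ABCI20 and linked variants that act on distant genes were not tested. Linkage and differences elsewhere in the genome stay open.

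Each comparison of 3 against 3 arrays has 10 splits, the real grouping included, which are too few for a share under 0.05. In total RNA 1 of 10 splits gave as many genes as the real grouping, 932, and the highest other gave 929. That other split set abci20 total replicate 1 with Col-0 total replicates 1 and 3 against the rest, and it points to a structure of the samples. Among the 3 other splits that part every pair of like-numbered arrays, the highest gave 887. The total RNA count alone therefore does not set a genotype effect apart from such structure. The real count was reached by 1 of 10 splits, and the highest other count was 0, for polysomal RNA (123), monosomal RNA (510), polysomal over total RNA in Col-0 (1985) and abci20 (6149), polysomal over monosomal RNA in Col-0 (3467) and abci20 (2994), and the genes shared by the 3 fractions (81). For the genotype differences, where the real count was 0 under limma with 1263 and 744 at an unadjusted p under 0.05, 10 of 10 splits gave as many. The highest other was 66 for polysomal over total RNA, with abci20 bulk 1 set with Col-0 bulks 2 and 3, which points to a structure of the samples, and 0 for polysomal over monosomal RNA. With the replicate block 971 genes passed in total RNA.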

How the results depend on the processing

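The alternatives with the 12 gradient arrays alone, without abci20 total replicate 1 outside the comparison, with identical probe sets kept, with scaling of the list tests, and all of those for shared genes were chosen only after the data were seen.

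With only the compared groups in the fit the counts were 0 for total, 423 for polysomal and 25 for monosomal RNA, 1590 for polysomal over total RNA in abci20 and 0 for shared genes. The main fit shares 1 spread per probe set, but the fractions differed in spread. Array weights, lower for noisier arrays, were 0.204 to 1.46 in total, 0.686 to 0.971 in monosomal and 1.1 to 5.33 in polysomal RNA. The main count may therefore be too low in polysomal RNA. For total RNA the direction is not settled: the count of 932 fell to 0 with only the compared groups but rose to 1326 with array weights. Quantile normalization gave 517 and 2575 for polysomal over total RNA in Col-0 and abci20 and 2070 for polysomal over monosomal RNA in Col-0. Centring gave 67 for polysomal and 316 for monosomal RNA, 3202 for polysomal over total RNA in Col-0 and 49 shared genes. The brighter probe sets gave 1701, 264 and 1087 for total, polysomal and monosomal RNA and 193 shared genes. The variance trend gave 1520, 286 and 970, and 194 shared genes. Array weights gave 2657 for polysomal RNA, 4899 and 11135 for polysomal over total RNA in Col-0 and abci20, 5496 and 7029 for polysomal over monosomal RNA, 2 for its genotype difference and 191 shared genes. The 12 gradient arrays gave 222 for polysomal RNA, 977 for monosomal RNA and 5384 for polysomal over monosomal RNA in Col-0. Without abci20 total replicate 1, outside the comparison, the counts were 215 for polysomal RNA, 955 for monosomal RNA and 3649 for polysomal over total RNA in Col-0. With 1 coefficient per group, leaving out arrays outside the compared groups changes no fitted difference. Those counts changed through the estimated spread and its degrees of freedom alone. For the other alternatives the cause was not tested.

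Leaving out each compared array gave 355 to 2640 for total, 27 to 70 for polysomal and 100 to 482 for monosomal RNA. It gave 426 to 1819 and 3076 to 9163 for polysomal over total RNA in Col-0 and abci20, 1730 to 3351 and 1475 to 2224 for polysomal over monosomal RNA, 0 to 28 for the genotype difference of polysomal over total RNA and 23 to 137 shared genes. The genotype difference of polysomal over monosomal RNA stayed at 0 under limma without each of its 12 arrays (744 at an unadjusted p under 0.05 with all). The highest counts for total RNA, polysomal over total RNA in abci20, its genotype difference and shared genes were those without abci20 total replicate 1. The cause was not tested.

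The replicate block moved no count by over 1.5 times: 971, 139, 569, 1762, 5983, 3390, 2950, 0 and 0 for the 9 comparisons and 94 shared genes. It kept 54 of 55 list calls, ended those of AT1G69900 (adjusted p = 0.0616) and AT1G22067 (0.0616) in total RNA and AT1G62620 (0.0661) in polysomal over total RNA in Col-0, and added SAP130a in abci20 (0.0399). With an estimated correlation 4 of 55 list calls held, all in polysomal RNA of abci20 against Col-0 (heat shock proteins, endoplasmic reticulum chaperones, abscisic acid and the ABCI family, whose call restates the loss of ABCI20), and 51 were lost. Over all alternatives, lists past the threshold in the main fit stayed past it in 759 cases and lost it in 147. Lists not past it in the main fit were left out of this tally, so it holds no new passes. Named genes kept their side of the threshold in 2173 cases, lost it in 150 and passed newly in 17, and 0 of those past the threshold changed sign. With only the compared groups in the fit, named genes kept their side in 118 cases and lost it in 38. The lost calls included every one in total RNA, that of ABCI20 among them. In 2 further cases AT1G15160 in abci20, which was not past the threshold (-0.62), changed sign, with array weights (0.03) and without abci20 polysome replicate 2 (0.002). Quantile normalization ended 16 list calls, centring 3 and the brighter probe sets 17. With identical probe sets kept, all 55 list calls stayed, and chloroplast-encoded genes passed in 2 more comparisons, polysomal RNA of abci20 against Col-0 (median 0.146, adjusted p = 0.0475) and polysomal over total RNA in abci20 (-0.481, adjusted p = 0.000164). Signal near background limits the folds of ABCI20, EXT10 and other genes whose lower group lies at such levels, among them AT5G19257, AT3G19615, NAC019, PTR5, ARL, PSBO2 and NRT2.6.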

Other observations

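The nitrate and clock lists were chosen only after genes of these groups had been seen among those higher in all 3 fractions. They were tested on their remaining members with predictions written before. In each fraction their p-values were adjusted over the nitrate and clock lists alone. These adjusted p-values are therefore not comparable with those of the lists fixed beforehand, which were adjusted over more lists.

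Other single genes past the threshold in all 3 fractions were chosen here after their values were seen and were not tested as a group. In total, polysomal and monosomal RNA the phosphoenolpyruvate carboxylase gene PPC2 was higher in abci20 by 1.66, 1.56 and 1.28 log2 and the carboxylase kinase gene PPCK1 by 1.83, 1.53 and 1.81. The flavonoid synthesis gene F3H was higher by 1.58, 1.05 and 1.58. The sugar transporter gene SWEET6 changed by -1.59, -1.02 and -1.18, the formate dehydrogenase gene FDH by -1.55, -0.86 and -0.76, and RSH3, of the chloroplast guanosine tetraphosphate pathway, by -1.94, -1.34 and -1.55.

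One hypothesis was that nitrate-response genes beyond NRT2.6, NIR1 and UPM1 are higher in abci20. The 19 remaining members had medians of 0.314, 0.264 and 0.133 log2 in total, polysomal and monosomal RNA, with adjusted p = 0.0043, 0.000403 and 0.128 (adjusted p = 0.0888, 0.0373 and 0.277 with an estimated correlation). The highest adjusted p, 0.128, missed the threshold that the hypothesis needed in every fraction, and the medians stayed above the bound of 0.1, so the hypothesis may hold and stays open. NIA1, a nitrate reductase gene, rose by 1.42 in total RNA (adjusted p = 0.011).

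A second hypothesis was that clock genes beyond the 4 first noticed changed in abci20. Of the 19 remaining members, 26.3% in total RNA, 26.3% in polysomal RNA and 31.6% in monosomal RNA had an unadjusted p under 0.05, against 17.5%, 7.95% and 14.9% of all genes. The lowest share, 26.3% (5 of 19), barely passed the bound of 25%, and the list test did not pass in any fraction (adjusted p = 0.886, 0.265 and 0.128). In total RNA these 5 members went both ways: CCA1 (0.88), TOC1 (0.60) and ELF4 (0.53) were higher, and GI (-0.55) and LKP2 (-0.63) lower. The prediction was met by its bound, but it rests on few members of mixed direction. A change of further clock genes stays open. The time of harvest, which is not given in the sources used here, was not tested.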
